A study of Homo sapiens with 35 samples.

How the data were processed

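Gene-level read counts of 35 RNA-seq libraries in 13 groups, named by the deposited labels, were analysed. The labels give the line, the guide or knockout, the treatment and a replicate number, but no dose or time for TPA. Nothing says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Library names carry clone number 1 in THP-1 sgControl and SKO and 3 in untreated U937 DKO, and none elsewhere, so the libraries of such a group may be repeats of 1 clone, and clone and label cannot be told apart. Cells were grown in RPMI-1640 medium, RNA was prepared with a column kit and poly(A) RNA was made into libraries with a directional kit, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with fastp 0.23.4, aligned to hg38 with STAR 2.7.11b and counted with Subread 2.0.6.

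The deposited counts are whole numbers per gene and are not normalized. Per the file headers, the authors counted the untreated U937 and THP-1 libraries with featureCounts 2.0.6 against GENCODE 38 by gene name, without strand, with paired reads counted singly and with reads that map to several places or overlap several genes left out. The deposited table of the TPA-treated U937, MOLM-13 and OCI-AML-3 libraries carries no counting command, but its 59428 gene rows had the same coordinates and lengths. Counting without strand means that reads of a gene and of an antisense partner cannot be told apart. Genes with near-identical copies, such as HLA, histone and ribosomal protein genes, lose or share reads. Of the rows, 698 are named by an Ensembl identifier and 75 have exons on more than 1 sequence. Transposable elements were not analysed here, because the counts are per gene. No deposited column was left unused. Counted reads per library ranged from 31985767 to 61178704. Replicate pairs of a group all differed by more than sampling noise.

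Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed its default expression filter, libraries were scaled by trimmed mean of M-values (TMM), and contrasts were tested with the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Each line and treatment had its own fit of all its groups without covariates, with 14915 genes for U937, 18585 for THP-1, 16246 for U937 under TPA, 15472 for MOLM-13 and 16175 for OCI-AML-3. The residual degrees of freedom were 6 with 9 libraries and 2 with 4 libraries. Effects of TPA and differences of effects were tested in fits of 18 libraries, with 16989 genes for U937 with and without TPA and 18715 for U937 and THP-1. Levels are in CPM, edgeR's unit of counts scaled to a library total. All are scaled by TMM within the fit, so that the same gene differs slightly between fits. Levels of the targeted genes in U937 are from the fit of U937 with and without TPA. Scaling by DESeq2's size factors moved the log2 fold changes of a comparison by a median of at most 0.061.

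The 28 gene lists were fixed before the data were examined. They hold interferon-stimulated genes, interferons and receptors, nucleic acid sensing, NF-kB inflammatory genes, MHC class I and class II presentation, immune ligands and checkpoints, monocyte and macrophage, granulocyte granule and progenitor genes, proliferation genes, p53 targets, heterochromatin machinery, numbered ZNF genes, germline genes, retrovirus- and transposon-derived genes, clustered protocadherins, stress and unfolded protein response, immediate early genes and lipid synthesis. Others mark other cell types (erythroid, megakaryocyte, lymphoid, stromal and dendritic) or RNA quality (mitochondrially encoded, ribosomal protein and histone genes). A list with at least 5 tested members was tested against the other genes with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. The test was repeated with an estimated correlation, and where a list passed the first and no second p is given, the call held. A member at 0 reads in a group was set at a floor of 3 reads over the group for a second median, given where it differs. The floor covers counting error only.

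The genes named were chosen by a rule fixed at the same time. It takes SUV39H1 and SUV39H2, up to 3 members of each list with the largest change past the test (2 for TPA and differences of effects), the 5 highest and 5 lowest changes among genes with a mean log2 CPM of at least 1 whose groups did not overlap, and up to 5 genes per direction shared by 3 lines. The text names part of them. Chromosome medians were added after the results had been seen. They use genes with a mean log2 CPM of at least 2, in bins of 20 Mb with at least 30 genes.

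Alternatives were other size factors, DESeq2 1.42.0 as the test, no filter on low counts, the replicate number as a block, only the compared groups or all libraries of a table in the fit, each library left out in turn, the estimated correlation and fry. Added after the data were seen were a term for a code in the library names and leaving out its libraries or shifted chromosomes. Simulated data with 50 genes changed per fold tested the steps, not the false share of the far more numerous real calls. At 1.5-fold, 90% were recovered for U937 SKO (14560 genes, 2.9% of 174 calls false) and 88% for MOLM-13 SKO (15097, 3.6%). The DKO effect under TPA minus untreated had 82% (16239, 2.6%). At 1.2-fold the shares were 54%, 38% and 32%.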

Results

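RNA-seq read counts per gene were deposited for 35 libraries of poly(A)-selected RNA from 4 human acute myeloid leukaemia cell lines. U937 and THP-1 are lines with monocytic features, and MOLM-13 and OCI-AML-3 are other lines of the same disease. In each line, libraries from cells given a control guide RNA (sgControl) were set against libraries labelled as lacking SUV39H1 (single knockout, SKO) or both SUV39H1 and SUV39H2 (double knockout, DKO). The products of these genes are histone methyltransferases that place trimethylation on lysine 9 of histone H3, a mark of heterochromatin. The series title names the question, which is whether the enzymes hold back an immune response set off by transposable elements. U937 and THP-1 each had 3 libraries per group for sgControl, SKO and DKO. U937 cells under a treatment called TPA in the labels had the same 3 groups with 3 libraries each. MOLM-13 had 2 sgControl and 2 SKO libraries, and OCI-AML-3 had 2 sgControl and 2 DKO libraries. Totals per library lay between 31985767 and 61178704 counted reads. The THP-1 DKO libraries (31985767 to 38678090 reads) were shallower than the THP-1 SKO libraries (56881318 to 61178704 reads).

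The targeted genes were examined in every library first. SUV39H1 lies on chromosome X from 48695554 to 48709016 and SUV39H2 on chromosome 10 from 14878820 to 14904315, both on the forward strand of hg38. In U937, SUV39H1 was at 65 ± 3.45 CPM (mean ± SD, n = 3) in sgControl, 110 ± 4.04 in the libraries labelled SKO and 81 ± 0.436 in those labelled DKO. CPM are counts scaled to the library's total by trimmed mean of M-values. THP-1 had 33.9 ± 2.38 CPM in sgControl, 92.4 ± 4.91 in SKO and 57 ± 0.577 in DKO (n = 3 each). Under TPA, U937 had 36.3 ± 1.14, 53.6 ± 2.79 and 22.4 ± 0.289 CPM in the same order. SUV39H1 was lower in MOLM-13 SKO, at 7.51 ± 0.707 CPM against 28 ± 1.84, and in OCI-AML-3 DKO, at 3.88 ± 1.17 against 39.7 ± 1.27 (n = 2 each).

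SUV39H2 went from 42.1 ± 2.04 CPM in U937 sgControl to 34.9 ± 0.794 in SKO and 32.1 ± 2.28 in DKO. In THP-1 it went from 30.6 ± 1.17 to 19.8 ± 0.917 and 14.2 ± 0.656 CPM, and under TPA from 19.9 ± 0.755 to 20.9 ± 0.493 and 9.96 ± 0.688. MOLM-13 SKO had 12.1 ± 0.849 CPM of SUV39H2 against 26.8 ± 1.2, and OCI-AML-3 DKO 21.3 ± 2.26 against 26.7 ± 3.68. The SUV39H1 transcript was therefore more abundant, not less, in both kinds of knockout library of untreated U937 and THP-1. Counts per gene do not see a small insertion or deletion that leaves the transcript in place, so they can neither bear out nor refute those labels, and the groups are called here by their labels.

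**Figure D1:**
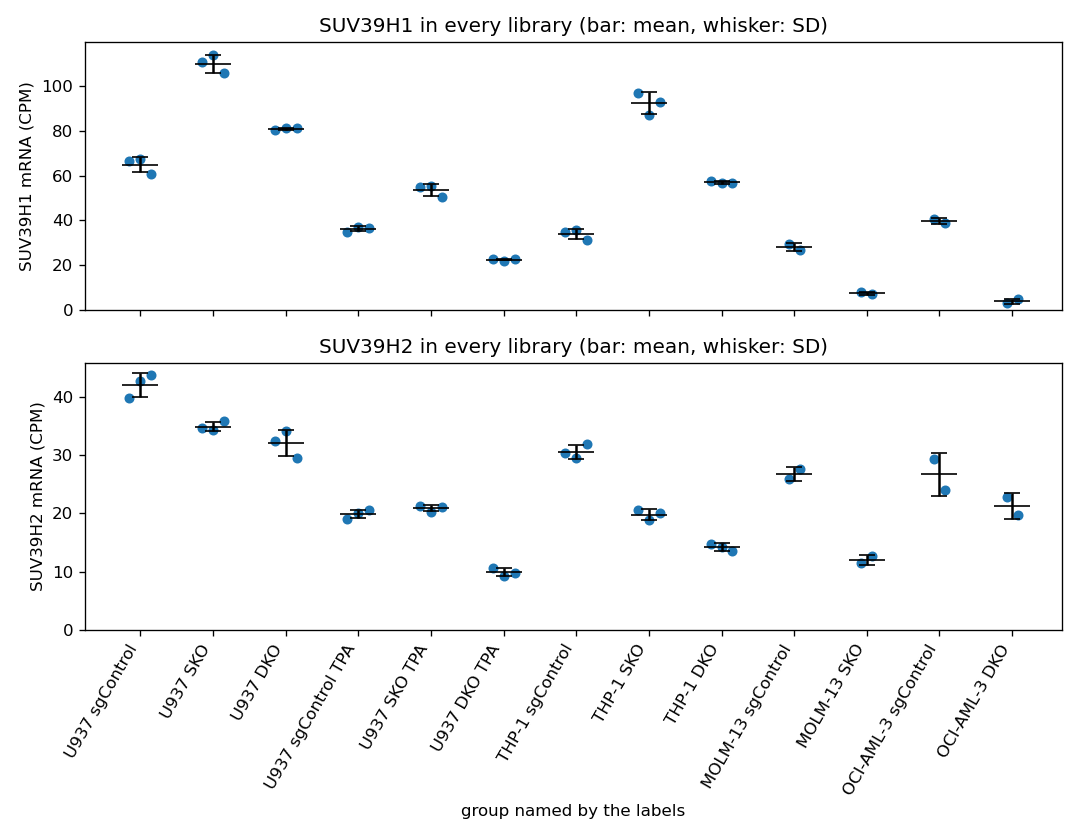
SUV39H1 (top) and SUV39H2 (bottom) in each library, in CPM (vertical axis from 0), by line and group (horizontal axis). Points are libraries, bars are group means and whiskers are the SD. SUV39H1 is at 110 CPM in U937 SKO against 65 in sgControl and falls from 39.7 to 3.88 CPM in OCI-AML-3 DKO.

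The first comparison asked which genes differed between the U937 libraries labelled SKO and sgControl, in which SUV39H1 itself was higher (0.76 ± 0.05 on the log2 scale, adjusted p = 1.2e-14 by edgeR's quasi-likelihood test). Genes of mature monocytes and macrophages rose as a group: 31 of 42 were higher and 5 lower (median 1.05, adjusted p = 3.9e-16). ITGAM, an integrin subunit of mature myeloid cells, rose by 4.07 ± 0.06, from 4.21 to 70.4 CPM (log2 fold change ± SE, and the mean of each group of 3 libraries scaled by trimmed mean of M-values). In the same list, the gelatinase gene MMP9 went the other way, -5.96 ± 0.34, from 7.52 to 0.115 CPM. Values below follow this order, with the reference group's level first, and a list's adjusted p is that of limma's camera. Where a group had at most a few reads, the levels ± SD stand alone, and a list's median is given again with members that had a group at 0 reads set at a floor of 3 reads. Immune ligands rose too, in 14 of 20 against 2 lower (median 0.61, adjusted p = 2.6e-06), among them CD276 (3 ± 0.08, 4.72 to 38 CPM) and CD70 (2.49 ± 0.11, 2.82 to 16 CPM), a ligand of the tumour necrosis factor family. CD70 lies on chromosome 19 below 20 Mb, where the median was 0.37 in SKO and 0.48 in DKO relative to all genes. Chromosome X had a median of 0.43 in SKO.

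Interferon-stimulated genes were split. Of 52, 29 rose and 5 fell (median 0.53, adjusted p = 0.0045, adjusted p = 0.058 with an estimated correlation). OAS2 (2.47 ± 0.15, 1.18 to 6.54 CPM), a sensor of double-stranded RNA, rose, while the chemokine gene CXCL11 (-3.36 ± 0.71) and GBP5 (-2.76 ± 0.2, 10.7 to 1.6 CPM) fell. Nucleic acid sensing had 11 higher and 7 lower of 24 (median 0, mean 0.1, tested upward, adjusted p = 0.4), with DHX58 (1.14 ± 0.31). In MHC class I presentation 17 of 23 rose and 3 fell (median 0.29, adjusted p = 0.049, adjusted p = 0.48 with an estimated correlation), with HLA-E (1.02 ± 0.04, 111 to 226 CPM). Values of HLA, histone and ribosomal protein genes are uncertain here and below, because near-identical copies share their reads. Among NF-kB inflammatory genes, 14 rose and 8 fell of 30 (median 0.21, adjusted p = 0.27), with the anti-apoptotic BCL2A1 (2.17 ± 0.06, 11.2 to 50.7 CPM) at the top.

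Cholesterol and fatty acid synthesis genes fell, 23 of 26 against 3 higher (median -0.49, adjusted p = 1.3e-06). FADS1 (-1.42 ± 0.04, 295 to 110 CPM), a fatty acid desaturase, and ACACA (-1.06 ± 0.05), encoding acetyl-CoA carboxylase, were lower, and INSIG1 (1.47 ± 0.03, 195 to 539 CPM), whose product retains the sterol-regulatory transcription factors, was higher. INSIG1 lies on chromosome 7 beyond 100 Mb, where bins of 20 Mb were higher by medians of 0.33 to 0.57. Of 25 progenitor genes 10 rose and 10 fell (median -0.18, adjusted p = 0.59), with the receptor gene FLT3 (-2.42 ± 0.17, 7.82 to 1.46 CPM) and KIT (-2.6 ± 0.46) down. Proliferation genes counted 18 up and 8 down of 40 (median 0.08, adjusted p = 0.59), with MKI67 (0.82 ± 0.05, 734 to 1300 CPM). Of 82 cytosolic ribosomal protein genes, 71 fell and 7 rose (median -0.51, adjusted p = 5e-13, adjusted p = 0.55 with an estimated correlation). Of the numbered ZNF genes, 101 of 371 rose and 138 fell (median -0.08, adjusted p = 0.46). Only 1 rose and 7 fell of 20 retrovirus- and transposon-derived genes (median -0.09, adjusted p = 0.44).

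Outside the lists, RAPGEF6 (0.0347 ± 0.0304 to 12.2 ± 1.23 CPM), a guanine nucleotide exchange factor, and SLC26A8 (5.29 ± 0.31) were among the genes that rose most, and ONECUT2 (37.9 ± 3.1 to 0.0344 ± 0.0298 CPM), a homeobox gene, and the tubulin gene TUBB6 (-8.05 ± 0.12, 89.3 to 0.342 CPM) among those that fell most. In all, 4573 of 14915 genes were higher and 4655 lower, and 1146 and 817 of these by at least 2-fold. Among the genes named for this comparison the largest adjusted p was 0.0018, for DHX58. Adjusted over the list alone, the higher and lower counts were 29 and 6 for interferon-stimulated genes, 32 and 5 for monocyte and macrophage genes and 102 and 138 for numbered ZNF genes, and the same for the other lists.

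In the U937 libraries labelled DKO, where SUV39H1 was again higher than in sgControl (0.32 ± 0.05), the interferon-stimulated list rose: 40 of 52 were higher and 6 lower (median 1.29, adjusted p = 6.1e-13). OAS2 (4.27 ± 0.14, 1.18 to 22.7 CPM) and HELZ2 (3.49 ± 0.1, 5.32 to 60.2 CPM) rose the most in that list. Genes of monocytes and macrophages rose in 35 of 42 and fell in 4 (median 1.58, adjusted p = 8.1e-26), and SIGLEC1 (7.96 ± 0.15, 0.235 to 61.2 CPM), a sialic acid receptor of macrophages, was among the highest. Immune ligands followed, 14 up and 1 down of 20 (median 0.81, adjusted p = 4.7e-07), with CD276 (3.05 ± 0.08) and CD70 (2.64 ± 0.11). Proliferation genes fell, 37 of 40 against 1 higher (median -0.57, adjusted p = 3.6e-13), with CENPE (-1.18 ± 0.05) and the replication helicase gene MCM7 (-1.29 ± 0.03, 858 to 351 CPM), which lies on chromosome 7. The 486 genes of that chromosome had a median of -0.42 relative to all genes, and those of chromosome X one of 0.38.

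Of 30 NF-kB inflammatory genes 13 rose and 8 fell (median 0.16, adjusted p = 0.039, adjusted p = 0.19 with an estimated correlation), with BCL2A1 (3.67 ± 0.06, 11.2 to 143 CPM) and the chemokine gene CXCL8 (2.65 ± 0.09, 5.53 to 34.9 CPM). MHC class II presentation had 11 higher and 3 lower of 15 (median 1.52, adjusted p = 0.0084, adjusted p = 0.093 with an estimated correlation), led by HLA-DRA (5.61 ± 0.23, 0.261 to 13.2 CPM). Class I had 13 and 5 of 23 (median 0.35, adjusted p = 0.089), with HLA-B (1.13 ± 0.03, 429 to 940 CPM). In nucleic acid sensing, 14 rose and 3 fell of 24 (median 0.26, adjusted p = 0.022, adjusted p = 0.14 with an estimated correlation), with DHX58 (2.59 ± 0.28) and SAMHD1 (1.19 ± 0.09). Interferons and receptors had 5 higher and 0 lower of 7 (median 0.56, adjusted p = 0.018, adjusted p = 0.093 with an estimated correlation), with IFNGR1 (1.2 ± 0.05). Granulocyte granule genes rose in 13 and fell in 5 of 19 (median 1.21, adjusted p = 4.1e-05, adjusted p = 0.093 with an estimated correlation), with CEACAM6 (7.75 ± 0.16, 0.263 to 56.7 CPM). For immediate early genes the counts were 20 and 6 of 29 (median 0.45, adjusted p = 0.0074, adjusted p = 0.093 with an estimated correlation), with KLF2 (5.82 ± 0.55), on chromosome 19, and JUN (2.53 ± 0.08, 15.9 to 91.8 CPM).

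Lymphoid genes, kept as markers of another cell type, fell in 16 of 20 with 0 higher (median -2.08, adjusted p = 0.02, adjusted p = 0.46 with an estimated correlation). Of 26 lipid synthesis genes 16 rose and 7 fell (median 0.23, adjusted p = 0.02, adjusted p = 0.093 with an estimated correlation), with INSIG1 (2.12 ± 0.03, 195 to 846 CPM), on chromosome 7, up and FADS1 (-1.07 ± 0.04) down. The list of p53 targets and apoptosis genes had 14 higher and 11 lower of 34, with a median of 0.08, a mean of -0.23 and adjusted p = 0.53. Its member PHLDA3 (-5.12 ± 0.48) was lower. Heterochromatin machinery fell in 19 and rose in 7 of 34 (median -0.21, adjusted p = 0.14), with the methyltransferase gene DNMT3A (1.04 ± 0.06) up and CBX3 (-1 ± 0.04), on chromosome 7, encoding a protein that binds the methylated lysine, down. Erythroid genes had 2 and 3 of 6 (median -0.24, adjusted p = 0.75). Retrovirus-derived genes had 2 and 6 of 20 (median -0.12, adjusted p = 0.53). Numbered ZNF genes had 119 and 100 of 371 (median 0.06, mean 0, tested downward, adjusted p = 0.97).

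DEFB1 (0 ± 0 to 34.7 ± 3.99 CPM), a defensin gene, was at 0 reads in sgControl, and CD180 (7.3 ± 0.15, 0.291 to 48 CPM) rose outside the lists. ONECUT2 (37.9 ± 3.1 to 0.019 ± 0.0329 CPM) was again near 0 reads in DKO, and IMPACT (23.4 ± 0.909 to 0 ± 0 CPM), on chromosome 18, had none. The test called 4956 genes higher and 5141 lower of 14915, 1717 and 1007 of them by at least 2-fold. Of named untargeted genes DHX58 had the largest adjusted p, 3.3e-09. Higher and lower counts adjusted over the list alone were 14 and 5 for nucleic acid sensing and 36 and 4 for monocyte and macrophage genes. They were 14 and 13 for the p53 and apoptosis list and 7 and 22 for heterochromatin machinery. Numbered ZNF genes had 118 and 100 and lymphoid genes 0 and 17, with no change in the other lists. The DKO libraries of untreated U937 carry no run date in their names while sgControl and SKO share one, so the run and the label cannot be told apart here.

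Set directly against SKO, the U937 DKO libraries had more of the interferon-stimulated transcripts, with 40 of 52 higher and 6 lower (median 0.69, adjusted p = 1.8e-16). IFIT1 (2.77 ± 0.16, 1.86 to 12.8 CPM) and IFI6 (2.62 ± 0.09, 14.3 to 88.3 CPM), both induced by type I interferon, rose. All 26 of the 26 genes for cholesterol and fatty acid synthesis were higher (median 0.7, adjusted p = 4.7e-37), with MSMO1 (1.27 ± 0.05) and DHCR7 (1.17 ± 0.04), enzymes of late sterol synthesis. Proliferation genes were lower in 38 of 40 and higher in 1 (median -0.7, adjusted p = 3.2e-50), with MKI67 (-1.05 ± 0.05, 1300 to 628 CPM). MHC class II presentation was higher in 10 and lower in 1 of 15 (median 1.73, adjusted p = 6.8e-06), with HLA-DRA (4.04 ± 0.19) and HLA-DMA (2.48 ± 0.26).

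The stress and unfolded protein response had 17 higher and 4 lower of 33 (median 0.2, adjusted p = 0.00023, adjusted p = 0.14 with an estimated correlation), with TRIB3 (1.55 ± 0.04, 112 to 330 CPM). Immediate early genes had 16 and 5 of 29 (median 0.3, adjusted p = 0.0011, adjusted p = 0.07 with an estimated correlation), with EGR3 (4.16 ± 0.22). The monocyte and macrophage list went 24 up and 11 down of 42 (median 0.61, adjusted p = 4.7e-12), SIGLEC1 (5.43 ± 0.12, 1.41 to 61.2 CPM) highest. Granule genes had 12 and 5 of 19 (median 0.68, adjusted p = 4.6e-09), with CEACAM6 (4.17 ± 0.11) and BPI (3.34 ± 0.37), a bactericidal granule protein gene. Numbered ZNF genes had 116 and 64 of 371 (median 0.12, adjusted p = 0.15), with ZNF431 (2.06 ± 0.08, 17.5 to 72.6 CPM). ALDOC (-4.17 ± 0.21, 6.09 to 0.336 CPM), an aldolase gene, and AMPH (-6.18 ± 0.28), on chromosome 7, were among the lowest. Chromosome 7 had a median of -0.56 relative to all genes, with 94% of its genes below theirs. SUV39H1 was lower in DKO than in SKO (-0.44 ± 0.05) and SUV39H2 did not pass the test (-0.12 ± 0.06, adjusted p = 0.11). The totals were 3592 higher and 3712 lower of 14915, with 707 and 344 at 2-fold or more. When adjusted over the list alone, higher and lower counts came to 40 and 7 for interferon-stimulated genes, 25 and 11 for monocyte and macrophage genes, 18 and 4 for stress response genes and 17 and 5 for immediate early genes, and the other lists kept theirs.

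THP-1 gave the opposite direction for interferon-stimulated genes. In the libraries labelled SKO, which had more SUV39H1 transcript than sgControl (1.44 ± 0.05), 56 of 60 of these genes were lower and 2 higher (median -1.46, adjusted p = 8.2e-81). IFIT1 (-6.36 ± 0.25, 18.4 to 0.224 CPM), on chromosome 10, and SIGLEC1 (-4.14 ± 0.12, 33.4 to 1.89 CPM), itself interferon-inducible, both dropped, and IFI27 went from 3.72 to 0.0247 CPM. MHC class I presentation fell in 17 of 23 and rose in 2 (median -0.42, adjusted p = 2.8e-08, adjusted p = 0.21 with an estimated correlation), with the peptide transporter gene TAP1 (-1.25 ± 0.05, 122 to 51.1 CPM) and PSMB9 (-1.12 ± 0.06), an immunoproteasome subunit. The receptor gene FLT3 (2.62 ± 0.05, 32.2 to 197 CPM) and ERG (3.22 ± 0.26), a transcription factor of haematopoietic progenitors, were higher in a progenitor list that had 13 up and 5 down of 28 (median 0.43, adjusted p = 5.1e-05, adjusted p = 0.083 with an estimated correlation).

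Nucleic acid sensing had 6 higher and 11 lower of 26 (median -0.13, adjusted p = 0.097), with DHX58 (-1.66 ± 0.15) down and TLR8 (2.28 ± 0.3) up. Monocyte and macrophage genes had 19 and 15 of 48 (median 0.03, adjusted p = 0.8), with S100A12 (5.36 ± 0.75) up. Immediate early genes fell in 17 and rose in 8 of 30 (median -0.34, adjusted p = 0.00039, adjusted p = 0.055 with an estimated correlation), with the transcription factor gene EGR1 (-3.1 ± 0.06, 118 to 13.8 CPM). The stress response list fell in 18 of 33 and rose in 2 (median -0.22, adjusted p = 0.001, adjusted p = 0.064 with an estimated correlation), with GDF15 (-2.94 ± 0.25) and HMOX1 (-2.29 ± 0.19), the gene of haem oxygenase. p53 targets had 8 higher and 14 lower of 33 (median -0.01, adjusted p = 0.052), with the cell cycle inhibitor gene CDKN1A (-2.61 ± 0.06, 126 to 20.5 CPM).

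Proliferation genes counted 12 up and 19 down of 40 (median -0.1, adjusted p = 0.21). MKI67 (-1.27 ± 0.04, 734 to 304 CPM) with KIF11 (-1.21 ± 0.05) and CDK1 (-1.08 ± 0.05) led the falls, and all 3 lie on chromosome 10, as do SUV39H2 and EGR2, where nearly the whole chromosome was lower. Over the 397 genes of chromosome 10 with enough reads, the median change was -0.96 in SKO and -0.97 in DKO, and 97.5% and 91.9% of them were below the median of all genes. Medians of the other chromosomes stayed between -0.05 and 0.07 in SKO and between -0.12 and 0.1 in DKO, relative to all genes.

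**Figure D2:**
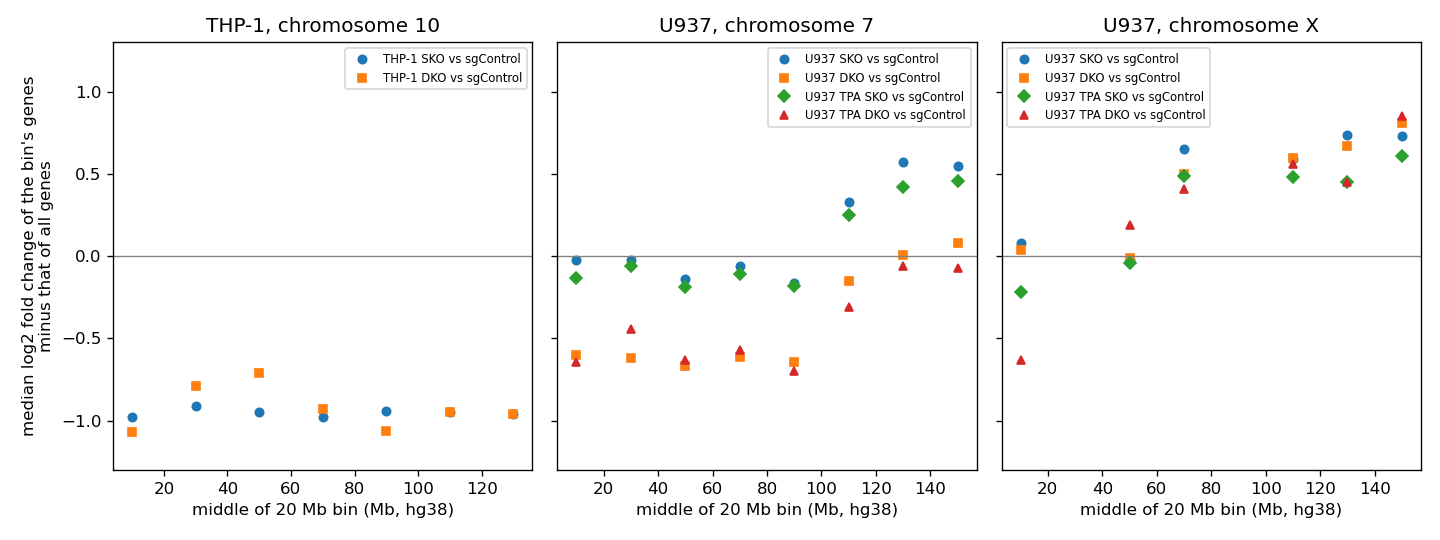
Median log2 fold change of the genes in each 20 Mb bin, minus that of all genes (vertical axis), against the middle of the bin in Mb of hg38 (horizontal axis), for chromosome 10 in THP-1 and chromosomes 7 and X in U937, with 1 symbol per comparison. The bins of chromosome 10 lie between -0.98 and -0.91 in THP-1 SKO and between -1.07 and -0.71 in DKO.

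POU4F2 (8.37 ± 0.24, 0.0665 to 21.5 CPM), a homeobox gene, and SLC12A7 (7.01 ± 0.16, 0.106 to 14 CPM) were among the genes that rose most outside the lists, PRDM6 (-5.86 ± 0.12, 68 to 1.16 CPM) and KCNQ5 (-6.55 ± 0.21) among those that fell most, and ADAMTS9 went from 37 to 0.0112 CPM. Ribosomal protein genes had 60 higher and 6 lower of 84 (median 0.19, adjusted p = 4.4e-05, adjusted p = 0.64 with an estimated correlation). Retrovirus-derived genes had 6 and 8 of 30 (median -0.04, adjusted p = 0.86). In total 3837 were higher and 4244 lower of 18585 genes, 939 and 988 by 2-fold or more. S100A12 had the largest adjusted p of the genes named for this contrast, 7.1e-07. The higher and lower counts adjusted over the list alone were 14 and 5 for progenitor genes, 13 and 21 for proliferation genes, 8 and 15 for p53 targets, 3 and 18 for stress response genes and 65 and 9 for ribosomal protein genes, with the other lists as given.

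The THP-1 libraries labelled DKO, whose SUV39H1 transcript was also above sgControl (0.75 ± 0.06), had fewer interferon-stimulated transcripts, with 47 of 60 lower and 6 higher (median -0.96, adjusted p = 5.3e-16). ISG15 (-3.06 ± 0.1, 41.2 to 4.95 CPM), a ubiquitin-like interferon product, fell, and the guanylate-binding protein gene GBP2 (3.45 ± 0.14, 1.5 to 16.3 CPM) rose. Against that, NF-kB inflammatory genes rose in 18 of 33 and fell in 6 (median 0.54, adjusted p = 0.0018), with the cytokine gene TNF (6.23 ± 0.1, 1.32 to 99.7 CPM) and the chemokine gene CCL2 (3.79 ± 0.22). STK31 (12.23 ± 0.13, 0.132 to 614 CPM), a germline kinase gene, rose in a list that counted 10 up and 3 down of 21 (median 0.76, adjusted p = 8.5e-05). MHC class I presentation fell in 19 of 23 with 0 higher (median -0.91, adjusted p = 1e-14, adjusted p = 0.064 with an estimated correlation), including the chaperone gene CALR (-1.7 ± 0.04, 2540 to 781 CPM).

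Proliferation genes fell in 35 and rose in 3 of 40 (median -0.62, adjusted p = 4.2e-13), with KIF11 (-1.55 ± 0.05) and CDK1 (-1.39 ± 0.05) on chromosome 10. The stress and unfolded protein response fell in 23 of 33 and rose in 6 (median -0.61, adjusted p = 4.5e-05), SDF2L1 (-2.37 ± 0.09) among them. Monocyte and macrophage genes had 29 higher and 12 lower of 48 (median 0.47, adjusted p = 3.4e-05, adjusted p = 0.17 with an estimated correlation), with the calcium-binding protein gene S100A9 (4.59 ± 0.07, 4.49 to 109 CPM). Numbered ZNF genes rose in 243 and fell in 86 of 477 (median 0.25, adjusted p = 0.003, adjusted p = 0.17 with an estimated correlation). Retrovirus-derived genes had 8 and 10 of 30 (median -0.1, adjusted p = 0.98), with ERVK13-1 (2.31 ± 0.13) up, and protocadherins 4 and 10 of 27 (median -0.15, adjusted p = 0.49), with PCDHGA12 (-4.65 ± 0.27) down. Lipid synthesis genes had 16 and 7 of 26 (median 0.49, adjusted p = 0.00021, adjusted p = 0.22 with an estimated correlation).

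Markers of other cells moved as well, with CLEC1B (4.87 ± 0.57) in the megakaryocyte list (8 up, 0 down of 10) (median 1.7, adjusted p = 0.1) and GNLY (-5.16 ± 0.19) in the lymphoid list (3 up, 4 down of 15) (median -0.18, adjusted p = 0.53). Mitochondrially encoded genes had 3 higher and 11 lower of 15 (median -0.34, adjusted p = 0.015, adjusted p = 0.5 with an estimated correlation). Histone genes had 10 and 4 of 23 (median 0.94, adjusted p = 0.27). SLC12A7 (8.52 ± 0.15, 0.106 to 39.8 CPM) rose and MAGED1 (-6.3 ± 0.15, 32.8 to 0.413 CPM) fell far, and CST7 (0 ± 0 to 12.1 ± 0.872 CPM) was at 0 reads in sgControl. The test called 5936 genes higher and 6254 lower of 18585, 3144 and 1291 by 2-fold or more. Adjusted p-values of these genes reached at most 1.1e-08, in CLEC1B. Adjusted over the list alone, the higher and lower counts were 19 and 6 for NF-kB inflammatory genes, 3 and 10 for protocadherins and 1 and 4 for lymphoid genes, and the same for the other lists. DKO libraries of THP-1 carry a later run date in their names than sgControl and SKO, which share one, so label and run cannot be told apart.

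Between the 2 knockout labels of THP-1, interferon-stimulated genes were higher in DKO, 44 of 60 against 7 lower (median 0.6, adjusted p = 1.4e-11), with IFI44L (3.68 ± 0.32, 0.185 to 2.42 CPM). NF-kB inflammatory genes were also higher, 17 against 5 of 33 (median 0.59, adjusted p = 3.4e-06), with TNF (4.59 ± 0.09, 4.13 to 99.7 CPM) and CCL3 (4.28 ± 0.43). Immediate early genes rose in 17 and fell in 1 of 30 (median 0.55, adjusted p = 1.1e-14), with EGR1 (3.92 ± 0.06) and EGR3 (3.42 ± 0.13). Germline genes had 9 higher and 3 lower of 21 (median 0.74, adjusted p = 3e-07), and STK31 went from 0.0229 to 614 CPM. Proliferation genes fell in 33 of 40 and rose in 2 (median -0.43, adjusted p = 7.1e-18), with UHRF1 (-1.14 ± 0.04, 254 to 116 CPM), whose product reads hemimethylated DNA, and the helicase subunit gene MCM5 (-1.05 ± 0.04).

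MHC class I presentation had 1 higher and 17 lower of 23 (median -0.44, adjusted p = 2.8e-08, adjusted p = 0.12 with an estimated correlation). Genes of monocytes and macrophages had 28 and 6 of 48 (median 0.51, adjusted p = 9.4e-10, adjusted p = 0.098 with an estimated correlation), with TREM1 (2.52 ± 0.28). The stress response list had 8 and 16 of 33 (median -0.21, adjusted p = 0.011, adjusted p = 0.11 with an estimated correlation), with the chaperone gene HSPA5 (-1.05 ± 0.04, 1040 to 502 CPM) down. Numbered ZNF genes were higher in 198 and lower in 70 of 477 (median 0.18, adjusted p = 0.0024, adjusted p = 0.12 with an estimated correlation). ERV3-1 (2.05 ± 0.13, 6.03 to 25 CPM), an envelope gene of retroviral origin, was higher in a list with 7 up and 9 down of 30 (median -0.06, mean 0.08, tested upward, adjusted p = 0.86). Higher genes numbered 4708 and lower genes 5293 of 18585, with 1935 and 298 at 2-fold or more. Among the genes named for this comparison the largest adjusted p was 5.2e-09, for TREM1. Counts adjusted over the list alone were 18 and 5 for NF-kB inflammatory genes, 2 and 17 for MHC class I presentation, 32 and 6 for monocyte and macrophage genes, 199 and 70 for numbered ZNF genes and 19 and 1 for immediate early genes, higher and lower, with no change in the other lists.

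Under TPA, the U937 libraries labelled SKO had more of nearly every interferon-stimulated transcript: 55 of 58 rose and 1 fell (median 2.24, adjusted p = 1.2e-183). OAS2 (5.69 ± 0.08, 2.38 to 124 CPM), IFIT1 (5.63 ± 0.07, 2.67 to 133 CPM) and GBP1 (6 ± 0.22, 0.109 to 7.39 CPM) rose the most. Nucleic acid sensing rose in 21 of 25 and fell in 1 (median 0.62, adjusted p = 2.4e-13), with IFIH1 (2.12 ± 0.04, 53.4 to 232 CPM), the gene of the RNA sensor MDA5. The monocyte and macrophage list rose in 31 and fell in 13 of 47 (median 0.54, adjusted p = 1.6e-16), with SIGLEC1 (7.25 ± 0.12, 1.57 to 241 CPM) and the scavenger receptor gene MSR1 (6.21 ± 0.11, 0.5 to 37 CPM) higher and MMP9 (-6.6 ± 0.11, 713 to 7.37 CPM) lower. SUV39H1 was higher in SKO (0.55 ± 0.05), and SUV39H2 did not pass the test (0.05 ± 0.07, adjusted p = 0.61).

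MHC class I presentation had 13 higher and 0 lower of 23 (median 0.26, adjusted p = 0.00083, adjusted p = 0.3 with an estimated correlation), with TAP1 (1.12 ± 0.05, 44.4 to 96.3 CPM). NF-kB genes counted 19 up and 10 down of 37 (median 0.22, or 0.21 at the floor, adjusted p = 0.017, adjusted p = 0.37 with an estimated correlation), with TNFAIP6 (-3.88 ± 0.15) down. Immune ligands had 15 and 3 of 24 (median 0.63, adjusted p = 0.00011, adjusted p = 0.074 with an estimated correlation), with the costimulatory gene CD86 (-2.89 ± 0.13, 14.6 to 1.96 CPM) down. Lipid synthesis genes fell in 20 and rose in 3 of 26 (median -0.31, adjusted p = 0.00018, adjusted p = 0.12 with an estimated correlation), FADS1 (-1.51 ± 0.05, 216 to 75.7 CPM) the most. Retrovirus-derived genes had 2 and 9 of 24 (median -0.18, adjusted p = 0.25), with ERV3-1 (3.48 ± 0.17, 0.715 to 7.97 CPM), on chromosome 7, up.

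Dendritic cell genes, listed as another cell type, had 5 higher and 3 lower of 11 (median -0.1, mean 0.28, tested upward, adjusted p = 0.077), with the chemokine receptor gene XCR1 (3.32 ± 0.18). Ribosomal protein genes fell in 57 and rose in 11 of 82 (median -0.22, adjusted p = 0.0034, adjusted p = 0.61 with an estimated correlation). ELAVL4 (8.22 ± 0.38) and PCYT1B (7.95 ± 0.39) rose outside the lists, and TUBB6 (-7.52 ± 0.34, 79.4 to 0.421 CPM) and CTIF (-7.31 ± 0.36) fell. IFNB1, the interferon beta gene, had no read in sgControl and 0.0963 CPM in SKO. In total 4185 were higher and 3998 lower of 16246 genes, 1097 and 697 by 2-fold or more. Apart from the targeted genes, no adjusted p of a gene named for it exceeded that of IFNB1, 0.0089. When adjusted over the list alone, higher and lower counts came to 22 and 2 for nucleic acid sensing, 15 and 5 for immune ligands, 3 and 21 for lipid synthesis genes and 11 and 59 for ribosomal protein genes, and the other lists kept theirs.

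In the TPA-treated libraries labelled DKO, SUV39H1 (-0.71 ± 0.06) and SUV39H2 (-1.01 ± 0.08) were both below sgControl. All 58 interferon-stimulated genes with enough reads rose (median 4.68, adjusted p = 1.1e-221, or 0.0033 with an estimated correlation). RSAD2 (9.57 ± 0.08, 0.982 to 758 CPM), the gene of the antiviral enzyme viperin, and GBP1 (10.68 ± 0.13, 0.109 to 190 CPM) showed the largest rises. Interferon transcripts themselves appeared: IFNB1 went from 0 to 2.75 CPM, IFNL1 from 0 to 2.71 and IFNA2 from 0 to 1.11. Their list had 8 higher and 0 lower of 10 (median 0.82, adjusted p = 0.0054, adjusted p = 0.055 with an estimated correlation). Nucleic acid sensing rose in 21 and fell in 2 of 25 (median 1.58, adjusted p = 4.2e-17), with IFIH1 (4.09 ± 0.04, 53.4 to 909 CPM) and DDX58 (4.37 ± 0.22), the gene of RIG-I.

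NF-kB inflammatory genes rose in 29 of 37 and fell in 5 (median 1.66, adjusted p = 4.1e-16), with the chemokine genes CCL4 (5.77 ± 0.07, 5.24 to 286 CPM) and CXCL8 (4.03 ± 0.04, 82.7 to 1350 CPM). MHC class I presentation rose in 22 and fell in 0 of 23 (median 1.26, adjusted p = 2.8e-17), with TAP1 (3.73 ± 0.05, 44.4 to 590 CPM) and HLA-E (2.68 ± 0.03, 269 to 1730 CPM). Immune ligands had 17 and 4 of 24 (median 0.75, adjusted p = 9.6e-08), with CD274 (7.03 ± 0.29, 0.0955 to 12.9 CPM). Monocyte and macrophage genes had 35 and 7 of 47 (median 1.1, adjusted p = 3.1e-21), with SIGLEC1 (9.68 ± 0.12, 1.57 to 1300 CPM). The chemokine gene CCL8 (12.24 ± 0.11, 0.146 to 712 CPM) rose outside these lists.

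Proliferation genes fell in 38 of 40 and rose in 1 (median -1.75, adjusted p = 5.2e-31, adjusted p = 0.059 with an estimated correlation), with MCM7 (-2.27 ± 0.07, 427 to 88.7 CPM) on chromosome 7, CCNE1 (-2.17 ± 0.12) and UHRF1 (-2.12 ± 0.05). p53 targets had 18 and 11 of 34 (median 0.15, adjusted p = 0.038, adjusted p = 0.084 with an estimated correlation), with CDKN1A (3.63 ± 0.04, 97.4 to 1200 CPM). Heterochromatin machinery had 10 and 22 of 35 (median -0.43, adjusted p = 0.005), with HELLS (-1.98 ± 0.09) and CHAF1B (-1.58 ± 0.07) down. The stress response list had 24 and 6 of 33 (median 0.67, adjusted p = 1.8e-06), with ATF3 (3.99 ± 0.05, 19.1 to 302 CPM). Immediate early genes had 26 and 1 of 29 (median 1.09, adjusted p = 5.6e-11), with NR4A3 (4.58 ± 0.1). Numbered ZNF genes had 97 and 151 of 378 (median -0.11, adjusted p = 0.35). Retrovirus-derived genes had 6 and 12 of 24 (median -0.3, adjusted p = 0.38), with ERV3-1 (3.23 ± 0.17), on chromosome 7.

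The RNA quality lists moved beside these: mitochondrially encoded genes fell in 15 of 15 (median -0.88, adjusted p = 1.2e-09, adjusted p = 0.084 with an estimated correlation), with MT-CO3 (-1.88 ± 0.03, 6490 to 1770 CPM), ribosomal protein genes fell in 71 and rose in 6 of 82 (median -0.79, adjusted p = 2.8e-17, adjusted p = 0.15 with an estimated correlation), and histone genes rose in 14 and fell in 2 of 20 (median 1.56, adjusted p = 0.039, adjusted p = 0.095 with an estimated correlation), with H2BC5 (3.67 ± 0.16). Markers of other cell types included GZMB (6.82 ± 0.4) among lymphoid genes (4 up, 3 down of 13) (median 0.2, adjusted p = 0.7) and PPBP (6.01 ± 0.18) among megakaryocyte genes (5 up, 1 down of 10) (median 0.58, adjusted p = 0.041, adjusted p = 0.11 with an estimated correlation). The test called 5541 genes higher and 5923 lower of 16246, 2438 and 2064 by 2-fold or more. IFNA2 had the largest adjusted p of the genes named for this contrast, 7.5e-08. The higher and lower counts adjusted over the list alone were 21 and 3 for nucleic acid sensing, 96 and 149 for numbered ZNF genes and 6 and 72 for ribosomal protein genes, with the other lists as given.

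The treated DKO libraries also exceeded the treated SKO libraries, with 57 of 58 interferon-stimulated genes higher and 0 lower (median 2.1, adjusted p = 1.4e-150), RSAD2 (6.26 ± 0.06, 9.86 to 758 CPM) the most. IFNB1 had 0.0963 CPM in SKO and 2.75 in DKO (4.78 ± 0.54), and interferons and receptors counted 8 up and 0 down of 10 (median 0.64, adjusted p = 0.0017). Sensing genes rose in 19 and fell in 3 of 25 (median 0.7, adjusted p = 4.3e-10), with AIM2 (2.53 ± 0.06, 13.2 to 76 CPM), a sensor of cytosolic DNA. MHC class I presentation rose in 22 and fell in 1 of 23 (median 1.19, adjusted p = 7.2e-19), with TAP1 (2.62 ± 0.05) and PSMB9 (2.15 ± 0.07). Immune ligands had 18 and 2 of 24 (median 0.65, adjusted p = 1.3e-05), with TNFSF10 (3.73 ± 0.06, 8.61 to 114 CPM), the gene of the death ligand TRAIL.

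NF-kB genes had 32 higher and 2 lower of 37 (median 1.37, adjusted p = 3.1e-20), with CCL4 (4.24 ± 0.06). Proliferation genes fell in 38 and rose in 1 of 40 (median -1.58, adjusted p = 2.9e-45), with GINS2 (-1.99 ± 0.09) and UHRF1 (-1.99 ± 0.05). Progenitor genes had 4 and 12 of 25 (median -0.68, adjusted p = 0.012), with the transcription factor gene MYB (-1.79 ± 0.04, 282 to 81.8 CPM) lower. Targets of p53 had 16 and 5 of 34 (median 0.3, adjusted p = 0.0011), with the caspase gene CASP1 (2.09 ± 0.08). Mitochondrially encoded genes fell in 15 of 15 (median -0.81, adjusted p = 7.7e-13), and histone genes rose in 12 and fell in 2 of 20 (median 2.06, adjusted p = 0.00039). CCL8 (5.42 ± 0.06, 16.6 to 712 CPM) rose, and ALDOC (-5.46 ± 0.32) and AMPH (-4.36 ± 0.28) fell, the last on chromosome 7, which had a median of -0.48. Counts were 5083 higher and 5264 lower of 16246, 1657 and 1423 at 2-fold or more. Adjusted p-values of these genes reached at most 2.1e-08, in IFNB1. Adjusted over the list alone, the higher and lower counts were 9 and 0 for interferons and receptors, and the same for the other lists.

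**Figure D3:**
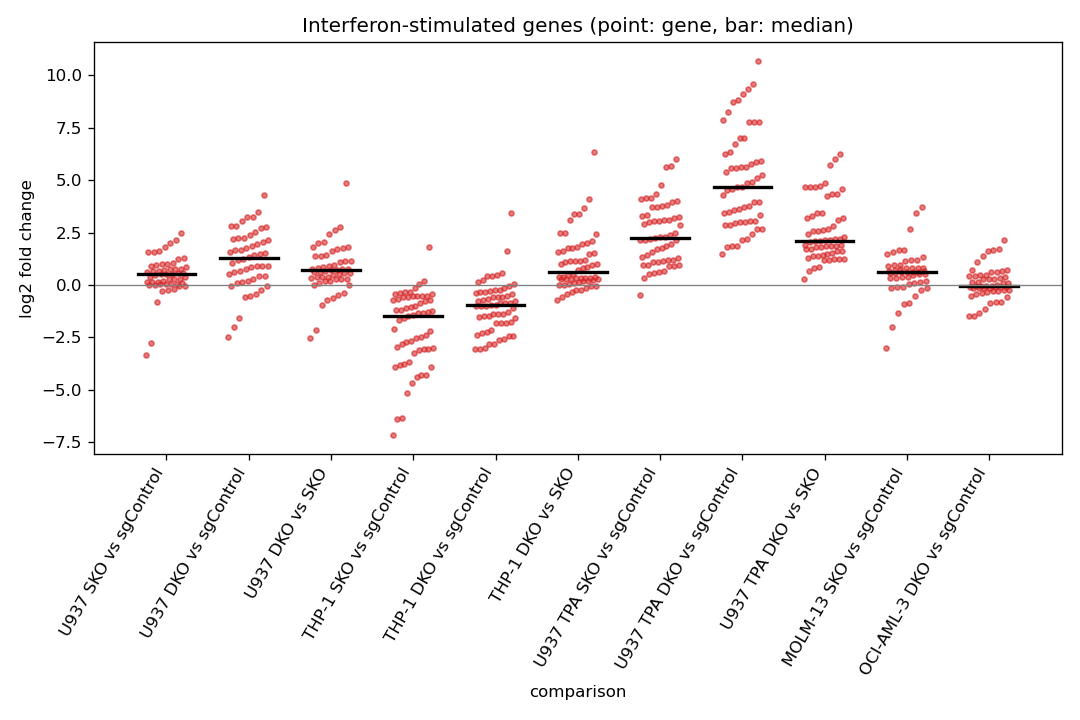
Log2 fold change (vertical axis) of each interferon-stimulated gene with enough reads, 1 point per gene, in each knockout comparison (horizontal axis), with bars at the medians; the values of genes with few reads in a group depend on the prior count. The median is -1.46 in THP-1 SKO and 4.68 in TPA-treated U937 DKO, both against sgControl.

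In MOLM-13 the SUV39H1 transcript fell in SKO (-1.9 ± 0.09), and so did SUV39H2 (-1.15 ± 0.08). Genes of monocytes and macrophages rose in 33 of 37 and fell in 2 (median 1.61, adjusted p = 9.3e-31, adjusted p = 0.068 with an estimated correlation), with the lysozyme gene LYZ (3.72 ± 0.02, 566 to 7480 CPM), with 2 libraries per group. Proliferation genes fell in 39 of 40 with 0 higher (median -1.58, adjusted p = 1.7e-74, adjusted p = 0.068 with an estimated correlation), including the cyclin gene CCNA2 (-1.89 ± 0.04, 158 to 42.9 CPM). MHC class II presentation rose in 12 and fell in 1 of 16 (median 2.56, adjusted p = 2.9e-08, adjusted p = 0.15 with an estimated correlation), with HLA-DRA (4.93 ± 0.09, 1.76 to 53.9 CPM) and HLA-DQB1 (5.09 ± 0.23). Interferon-stimulated genes had 33 higher and 8 lower of 50 (median 0.6, adjusted p = 0.0022, adjusted p = 0.15 with an estimated correlation), with OAS2 (3.73 ± 0.77) and RSAD2 (3.42 ± 0.39) up and IFITM1 (-3 ± 0.17, 9.85 to 1.23 CPM) down.

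Class I presentation had 15 up and 6 down of 23 (median 0.39, adjusted p = 6e-04, adjusted p = 0.17 with an estimated correlation), with HLA-B (1.77 ± 0.03, 336 to 1140 CPM). NF-kB genes had 21 and 4 of 29 (median 0.55, adjusted p = 0.0084, adjusted p = 0.18 with an estimated correlation), with CXCL8 (3.67 ± 0.12). Sensing genes had 15 and 3 of 24 (median 0.27, adjusted p = 0.0016, adjusted p = 0.18 with an estimated correlation), with SAMHD1 (1.91 ± 0.03, 71.2 to 269 CPM). Immediate early genes had 17 and 3 of 28 (median 0.43, adjusted p = 1e-06, adjusted p = 0.15 with an estimated correlation), with FOS (3.69 ± 0.06). Of 33 p53 targets 23 rose and 7 fell (median 0.53, adjusted p = 5.3e-07, adjusted p = 0.15 with an estimated correlation), with BTG2 (2.5 ± 0.06). Lipid synthesis genes had 2 and 20 of 27 (median -0.28, adjusted p = 4.4e-07, adjusted p = 0.15 with an estimated correlation), with the desaturase gene FADS2 (-3.5 ± 0.05, 148 to 13.1 CPM). Stress genes had 8 and 22 of 33 (median -0.33, adjusted p = 8.7e-05, adjusted p = 0.15 with an estimated correlation), with PHGDH (-3.93 ± 0.07, 83.6 to 5.53 CPM), the entry enzyme of serine synthesis, down and HMOX1 (3.77 ± 0.25) up.

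Heterochromatin machinery had 7 higher and 22 lower of 35 (median -0.26, adjusted p = 0.001, adjusted p = 0.15 with an estimated correlation), with CHAF1B (-1.62 ± 0.08) down. Numbered ZNF genes had 185 and 80 of 400 (median 0.2, adjusted p = 0.06), and ZNF91 went from 0.0248 to 11.2 CPM. Retrovirus-derived genes had 10 and 8 of 25 (median 0.11, adjusted p = 0.8), with ERV3-1 (3.68 ± 0.26) up and RTL8B (-4.68 ± 0.39) down. PEG3 (7.99 ± 0.41) and OLR1 (5.24 ± 0.35) rose outside the lists, and SKIDA1 (-8.15 ± 0.19, 33.3 to 0.117 CPM) and NCAM1 (-6.56 ± 0.21, 17 to 0.179 CPM) fell. The test called 4926 higher and 4977 lower of 15472 genes, 1839 and 912 by 2-fold or more. Among the genes named for this comparison the largest adjusted p was 8.6e-05, for OAS2. Counts adjusted over the list alone were 13 and 1 for MHC class II presentation, higher and lower, with no change in the other lists.

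OCI-AML-3 had the largest fall of SUV39H1 (-3.35 ± 0.12) and a smaller one of SUV39H2 (-0.33 ± 0.09). The monocyte and macrophage list rose in 30 of 42 and fell in 5 (median 1.11, adjusted p = 4.9e-37, adjusted p = 0.11 with an estimated correlation), with S100A8 (3.52 ± 0.07, 12 to 137 CPM), with 2 libraries per group. Proliferation genes fell in 39 of 40 with 0 higher (median -1.08, adjusted p = 2.4e-55, adjusted p = 0.076 with an estimated correlation), including the topoisomerase gene TOP2A (-1.38 ± 0.05, 499 to 191 CPM). p53 targets rose in 26 and fell in 6 of 35 (median 0.69, adjusted p = 1.1e-14, adjusted p = 0.11 with an estimated correlation), with CDKN1A (3.12 ± 0.06, 30.5 to 265 CPM) and TP53INP1 (2.68 ± 0.13). Interferon-stimulated genes did not move as a group: 16 rose and 13 fell of 53, the median was -0.04 and the mean 0.08, the test pointed up, and adjusted p = 0.25. TRIM22 (2.14 ± 0.07, 31.2 to 137 CPM) rose.

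Class I presentation had 8 higher and 6 lower of 23 (median 0.01, adjusted p = 0.37), with HLA-B (0.63 ± 0.05), and class II 4 and 1 of 10 (median 0.2, adjusted p = 0.33), with HLA-DRA (2.12 ± 0.48). NF-kB genes had 16 and 5 of 31 (median 0.41, adjusted p = 5e-04, adjusted p = 0.23 with an estimated correlation), with BCL2A1 (1.97 ± 0.13). Stress genes had 7 and 18 of 33 (median -0.21, adjusted p = 3.9e-05, adjusted p = 0.27 with an estimated correlation), with PHGDH (-3.21 ± 0.08, 89.5 to 9.69 CPM) down. Heterochromatin machinery had 4 and 20 of 35 (median -0.24, adjusted p = 0.00024, adjusted p = 0.2 with an estimated correlation), with HELLS (-1.19 ± 0.09) down. Numbered ZNF genes had 139 and 87 of 431 (median 0.1, adjusted p = 0.25), with ZNF525 (6.34 ± 0.25, 0.154 to 12.6 CPM) up.

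Retrovirus-derived genes had 6 higher and 10 lower of 24 (median -0.01, adjusted p = 0.6). Stromal genes had 2 and 3 of 9 (median 0.32, mean -0.32, tested upward, adjusted p = 0.084), with ACTA2 (2.28 ± 0.18). Histone genes rose in 19 and fell in 4 of 36 (median 1.33, adjusted p = 7.2e-09, adjusted p = 0.13 with an estimated correlation). DYSF (6.3 ± 0.27), the dysferlin gene, rose and S100A16 (-5.38 ± 0.16, 26 to 0.622 CPM) fell outside the lists, and CRISPLD1 (4.79 ± 0.045 to 0 ± 0 CPM) had no read in DKO. The test called 3931 higher and 4134 lower of 16175 genes, 1070 and 770 by 2-fold or more. Of named untargeted genes HLA-DRA had the largest adjusted p, 0.00023. When adjusted over the list alone, higher and lower counts came to 17 and 5 for NF-kB inflammatory genes, 9 and 6 for MHC class I presentation and 3 and 3 for stromal genes, and the other lists kept theirs. Without DKO replicate 1 the number of higher genes was 2277 and without replicate 2 it was 2192, where the remaining library is assumed to vary like the other group.

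Which genes moved the same way in several lines was counted over the genes tested in all of them, in comparisons with no library in common. Of 13418 genes, 889 were higher in DKO in U937, THP-1 and OCI-AML-3, where independent calls would give 349.9, and 1552 were lower, against 548.8. Higher in all 3 were ATP6V0D2, a subunit gene of the proton pump of lysosomes (5.7, 4.43 and 3.39 in U937, THP-1 and OCI-AML-3), the low-affinity IgE receptor gene FCER2 (3.2, 3.21 and 3.82) and S100A8 (2.83, 3.93 and 3.52). Lower in all 3 were the telomerase gene TERT (-5.92, -1.57 and -2.55), LGALS3BP (-1.66, -3.45 and -1.94) and HMX3 (-4.39, -3.75 and -2.19), the last on chromosome 10. For SKO, 603 of 13192 genes were higher in U937, THP-1 and MOLM-13, against 305.8, and 737 lower, against 396.3. ADGRE1, a macrophage receptor gene (2.86, 1.9 and 2.23), S100A8 (2.28, 2.52 and 2.62) and LILRB3 (2.27, 2.03 and 2.07) were higher, and NCAM1 (-1.35, -1.62 and -6.56) and TERT (-3.18, -1.17 and -3.11) lower.

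Pairs of lines overlapped more than independent calls would in both directions (Fisher's exact test, p adjusted over pairs at most 6e-05). DKO calls shared by U937 and OCI-AML-3 had odds ratios of 3.03 for higher genes (1778 against 1120) and 3.56 for lower (2160 against 1342.9). The lower genes of THP-1 and OCI-AML-3 had 3.98 (2507 against 1530.9). Those of SKO in U937 and THP-1 had 1.29 for higher genes (1142 against 1001.4) and 1.18 for lower (1239 against 1141.4). With at least 2-fold change the odds ratios were 7.52, 3.35, 4.28, 2.9 and 2.81 in this order. Genes are not independent, so these p-values are too small. Well-expressed genes may be called in every line and no level-matched baseline was run, so excess overlap alone shows no shared effect.

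What TPA did in each group of U937 libraries was tested against the untreated libraries of the same label, which stand in a separate deposited table, so that treatment and preparation cannot be told apart. In sgControl, monocyte and macrophage genes rose in 37 of 48 and fell in 5 (median 2.5, or 2.32 at the floor, adjusted p = 1.6e-49), with SPP1 (12.76 ± 0.06, 0.736 to 5090 CPM), the osteopontin gene. NF-kB genes rose in 32 and fell in 2 of 37 (median 2.57, or 2.45 at the floor, adjusted p = 2.3e-26), with IER3 (6.82 ± 0.1, 0.465 to 52.2 CPM), and interferon-stimulated genes in 36 against 13 of 59 (median 0.7, adjusted p = 0.011, adjusted p = 0.36 with an estimated correlation). CDKN1A (4.54 ± 0.07, 4.23 to 98.4 CPM) rose in a p53 list of 17 higher and 10 lower of 35 (median 0.46, adjusted p = 0.025, adjusted p = 0.2 with an estimated correlation), and CTSG (-6.25 ± 0.05, 2520 to 33.1 CPM), the cathepsin G gene of granules, fell. Proliferation genes had 4 and 33 of 40 (median -0.64, adjusted p = 5.2e-08, adjusted p = 0.29 with an estimated correlation), with GINS2 (-1.44 ± 0.06). The counts were 5871 higher and 5638 lower of 16989. GINS2 had the largest adjusted p of the genes named in this paragraph for that contrast, 4.3e-21. No count of these lists changed when adjusted over the list alone.

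In SKO the interferon-stimulated list rose in 52 and fell in 3 of 59 (median 2.43, adjusted p = 1.9e-68), with CXCL10 (9.03 ± 0.28). Monocyte and macrophage genes had 39 higher and 9 lower of 48 (median 2.05, or 1.92 at the floor, adjusted p = 1.1e-50), with CD163 (11.44 ± 0.13, 0.0735 to 207 CPM), a haemoglobin scavenger receptor gene, and SPP1 (17 ± 0.08, 0.125 to 16700 CPM). CTSG (-3.62 ± 0.04, 1410 to 115 CPM) fell, and 5354 genes were higher and 5328 lower of 16989. Adjusted over the list alone, the higher and lower counts were 53 and 3 for interferon-stimulated genes, and the same for the other lists.

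In DKO all 59 of 59 interferon-stimulated genes rose (median 4.2, or 4.07 at the floor, adjusted p = 8.2e-102), and IFI44L went from 0.0189 to 88.8 CPM. Class I presentation had 21 higher and 0 lower of 23 (median 1.42, adjusted p = 2.5e-09). Proliferation genes had 1 and 38 of 40 (median -1.65, adjusted p = 1.4e-23), with GINS2 (-2.69 ± 0.08). CDKN1A (6.48 ± 0.06, 13.8 to 1230 CPM) and SPP1 (15.41 ± 0.07, 0.678 to 29900 CPM) rose, and the defensin gene DEFB1 (-4.91 ± 0.18, 34 to 1.13 CPM) fell. The totals were 6271 and 6142 of 16989. These list counts were all the same when adjusted over the list alone.

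Whether the SKO effect in U937 differed with TPA was tested as an interaction, in which an additive difference between the tables drops out. Interferon-stimulated genes had a larger SKO effect under TPA in 48 of 59 and a smaller one in 1 (median 1.69, adjusted p = 8.6e-86), with IFIT1 (5.71 ± 0.21). Sensing genes had 14 and 3 of 26 (median 0.41, adjusted p = 1.7e-07), with IFIH1 (2.16 ± 0.07) and TLR3 (3.02 ± 0.46). Granule genes had 10 and 1 of 22 (median 0.47, or 0.34 at the floor, mean -0.18, tested upward, adjusted p = 1.3e-06), with CTSG (2.62 ± 0.06). Genes of monocytes and macrophages had 12 and 21 of 48 (median -0.36, or -0.19 at the floor, adjusted p = 3.6e-16), with SIGLEC1 (4.73 ± 0.7). Of 16989 genes 3338 were above 0 and 3067 below. Adjusted p-values of these genes reached at most 1.4e-06, in TLR3. When adjusted over the list alone, higher and lower counts came to 49 and 1 for interferon-stimulated genes, 13 and 22 for monocyte and macrophage genes and 10 and 2 for granule genes, and the other lists kept theirs.

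For DKO the interaction was above 0 in 58 of 59 interferon-stimulated genes and below in 0 (median 3.26, adjusted p = 1.5e-136), with IFI44 (8.1 ± 0.74). NF-kB genes had 26 and 3 of 37 (median 1.37, or 1.23 at the floor, adjusted p = 8.3e-09), with CCL4 (6.89 ± 1.09). Class I presentation had 22 and 1 of 23 (median 1.3, adjusted p = 4.9e-29), with TAP1 (3.38 ± 0.07). Sensing genes had 18 and 4 of 26 (median 0.77, adjusted p = 1.6e-15). The monocyte and macrophage list had 12 and 20 of 48 (median -0.26, or -0.08 at the floor, adjusted p = 1.2e-06). Proliferation genes had 0 above and 38 below of 40 (median -1.11, adjusted p = 4.9e-29), with E2F1 (-1.5 ± 0.1), a regulator of S-phase entry, and KIF11 (-1.5 ± 0.07). In all, 3695 genes were above 0 and 4730 below of 16989 (4161 and 4210 with DESeq2's size factors, 4131 and 4068 with DESeq2). Among the genes named for this comparison the largest adjusted p was 1.7e-06, for CCL4. The higher and lower counts adjusted over the list alone were 28 and 3 for NF-kB inflammatory genes and 14 and 22 for monocyte and macrophage genes, with the other lists as given.

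The difference between the lines was tested in the same way, on the untreated libraries of both. The SKO effect on interferon-stimulated genes was higher in U937 than in THP-1 for 52 of 60 and lower for 3 (median 2.13, or 2.08 at the floor, adjusted p = 9.1e-43), with IFI44L (6.65 ± 0.84). Immediate early genes had 17 and 6 of 30 (median 1.04, adjusted p = 0.0029), with EGR2 (4.67 ± 0.43) on chromosome 10. Immune ligands had 14 and 3 of 25 (median 0.6, adjusted p = 1.1e-06), with CD276 (3.49 ± 0.09). Monocyte and macrophage genes had 25 and 10 of 47 (median 0.75, or 0.71 at the floor, adjusted p = 1.9e-11), with SIGLEC1 (6.68 ± 0.31). FLT3 (-5.02 ± 0.11) and KIT (-4.6 ± 0.29) were lower. In all, 4514 genes were above 0 and 4256 below of 18715. Fewer were above than below without U937 sgControl replicate 3 (3817 and 4681), U937 SKO replicate 2 (3857 and 4553) or U937 SKO replicate 3 (3880 and 4644). No adjusted p of a gene named for it exceeded that of IFI44L, 2.3e-08. Adjusted over the list alone, the higher and lower counts were 53 and 4 for interferon-stimulated genes, and the same for the other lists.

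The DKO effect on interferon-stimulated genes was higher in U937 for 47 of 60 and lower for 4 (median 1.94, adjusted p = 3.1e-36), with OAS2 (6.76 ± 0.15). Stress genes had 27 and 5 of 33 (median 1.27, adjusted p = 6.2e-09), with GDF15 (6.57 ± 0.63), on chromosome 19. Class I presentation had 21 and 1 of 23 (median 1.09, adjusted p = 4.5e-15), with HLA-F (5.04 ± 0.4). Sensing genes had 18 and 2 of 27 (median 0.52, adjusted p = 0.00083). Immune ligands had 14 and 5 of 25 (median 0.91, or 0.82 at the floor, adjusted p = 1.6e-05). Genes of monocytes and macrophages had 25 and 11 of 47 (median 0.68, adjusted p = 2.1e-10), with SIGLEC1 (10.24 ± 0.21). TNF (-6.19 ± 0.2) was lower in U937. In all, 5562 genes were above 0 and 4617 below of 18715. At 2-fold or more these were 2137 and 2461. Without U937 sgControl replicate 3 they were 4675 and 5144, and without U937 DKO replicate 1, 2 or 3 they were 4822 and 5102, 4691 and 5127, and 4734 and 5065. GDF15 had the largest adjusted p of the genes named for this contrast, 3e-11. Counts adjusted over the list alone were 47 and 5 for interferon-stimulated genes, higher and lower, with no change in the other lists.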

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

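The tests of scaling, of an effect in every line, of the list's members on chromosome 10, of run dates, of clones, of preparation and of the U937 chromosome segments were chosen only after the results were seen. No group had enough libraries for a test of outlying samples.

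In the interaction tests, 20 gene list effects differed between conditions or lines, each given as the median difference of effects. The SKO effect in U937 was larger under TPA for interferon-stimulated genes (1.69), nucleic acid sensing (0.41) and granule genes (0.47, or 0.34 at the floor, with a mean of -0.18), and lower for monocyte and macrophage genes (-0.36, or -0.19 at the floor). The DKO effect was larger under TPA for interferon-stimulated genes (3.26), NF-kB inflammatory genes (1.37, or 1.23 at the floor), MHC class I presentation (1.3) and nucleic acid sensing (0.77), and lower for monocyte and macrophage genes (-0.26, or -0.08 at the floor) and proliferation genes (-1.11). The SKO effect was higher in U937 than in THP-1 for interferon-stimulated genes (2.13, or 2.08 at the floor), immediate early genes (1.04), monocyte and macrophage genes (0.75, or 0.71 at the floor) and immune ligands (0.6). The DKO effect was higher in U937 for interferon-stimulated genes (1.94), stress and unfolded protein response (1.27), MHC class I presentation (1.09), immune ligands (0.91, or 0.82 at the floor), monocyte and macrophage genes (0.68) and nucleic acid sensing (0.52).

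The first pattern is the lower level of chromosome 10 in the THP-1 libraries labelled SKO and DKO. An effect of the enzymes in every line is argued against by a median of -0.07 at most in the other lines. A copy lost in both labels, or gained in the shared sgControl, predicts a like fall along the whole chromosome. The smallest fall of a bin was -0.71, so either is a candidate explanation that RNA alone cannot settle. In U937 DKO, the 11 bins shifted by 0.4 or more, on chromosomes 7, 18, 19 and X, kept their side under TPA. Segments the cultures carried and a knockout effect in this line would both last. Genes on these parts may have moved with their chromosome, not the labelled knockout. Chromosome 6 (median 0.15 in U937 DKO, 0.22 under TPA), among others, was not binned.

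The second pattern is the fall of interferon-stimulated genes in THP-1, against their rise in U937. It did not rest on members on chromosome 10 (SKO median -1.33 without them). The SKO libraries, with a median of -1.46, share the date code of sgControl, so that code cannot account for their fall. A shared code does not show a shared culture or preparation. For DKO (-0.96) the run date, and for SKO a difference between single clones (1 clone number in the names of its libraries and of those of sgControl), cannot be told apart from the label. The list's members were higher in THP-1 sgControl than in U937 sgControl by a median of 2.21 (log2 CPM), so an interferon state of that control culture may account for the fall, but a higher baseline of the line itself would give the same value. An effect of the labelled knockout or of chromosome 10's fall stays open too.

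The third pattern is the larger interferon effect of DKO under TPA. A scaling error is argued against by a median difference of effects of 3.32 with DESeq2's size factors. The untreated DKO libraries carry no run date, unlike sgControl and SKO, and although all 40 members called higher there were also called higher under TPA (100%), so were the 12 others, so the measure decides nothing and that preparation and the label cannot be told apart. TPA and the separate preparation of the treated libraries remain open, as do lower SUV39H1 and SUV39H2 transcripts in the treated DKO libraries.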

How the results depend on the processing

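The name-code term, the libraries left out for that code, the shifted chromosomes left out and the 2-fold limit on counts were chosen after the data were seen; all other alternatives were planned. Counts of genes higher and lower stayed within 1.5 times of the reported ones under each alternative other than that limit, except the 3931 genes higher in OCI-AML-3 DKO, which came to between 2192 and 3005 when 1 library was left out (2277 without DKO replicate 1 and 2192 without DKO replicate 2); fewer samples were then left, and the lone library is assumed to vary like the others. Which direction held more genes turned under at least 1 alternative in every comparison but the TPA response in DKO and the SKO effect with TPA; the cause was not tested. The interferon-stimulated list kept its direction and its side of the threshold except as follows. With the estimated correlation its call was lost in U937 SKO (0.53, adjusted p = 0.058) and MOLM-13 SKO (0.6, adjusted p = 0.15). It was also lost in the TPA response of sgControl (0.7, adjusted p = 0.36). Where it held, adjusted p was 1.1e-06 to 0.021. In OCI-AML-3 DKO its median changed sign to 0.06 without sgControl replicate 2, and the range over the libraries left out was -0.07 to 0.06. In U937 SKO, MT-RNR1 (-0.42) changed sign to 0.13 without sgControl replicate 2 (range -0.64 to 0.13) and 0.15 without the libraries with the code. The causes were not tested.

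Among named genes, DESeq2 lost 46 calls and kept 1502, and leaving out 1 library at a time lost 368, gained 1 and kept 10092. The replicate numbers did not pair the libraries: same-numbered libraries correlated between -0.049 and 0.253 in U937, -0.038 and 0.197 in THP-1, -0.041 and 0.089 under TPA, at 0.06 in MOLM-13 and at -0.034 in OCI-AML-3. With the replicate number as a block, U937 SKO had 4574 higher and 4665 lower genes, OCI-AML-3 DKO 3885 and 4109, and 8 of the named-gene calls were lost. Depth limits genes with a few reads in a group, whose fold changes depend on the prior count.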

Other observations

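The test of numbered ZNF genes was written before its result was seen, on a pattern found in the data. The grouping of splits by whether the labels of 1 condition or line stayed whole was added after their counts were seen.

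In TPA-treated against untreated U937 sgControl libraries, 13 of 22 granule genes fell and 5 rose (median -1.39, adjusted p = 5.3e-11), and platelet genes counted 6 up and 0 down of 11 (median 0.89, adjusted p = 0.17), with the von Willebrand factor gene VWF (9.98 ± 0.26). KIT (-4.82 ± 0.75) fell, and CD209 (0.034 ± 0.0299 to 1.51 ± 0.302 CPM), a C-type lectin gene of dendritic cells and macrophages, rose. Adjusted p-values of these genes reached at most 5.6e-07, in KIT. With p-values adjusted over the list alone, no count of these lists changed.

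In MOLM-13 SKO, histone genes rose in 18 and fell in 2 of 29 (median 1.31, adjusted p = 0.0063, adjusted p = 0.18 with an estimated correlation), with near-identical copies among them. EPX (-2.02 ± 0.03, 1070 to 264 CPM), the eosinophil peroxidase gene, and GATA2 (-1.4 ± 0.03, 300 to 114 CPM), a transcription factor gene of progenitors, fell. Of the 2 genes named here the larger adjusted p was 2.1e-26, for GATA2. No count of these lists changed when adjusted over the list alone.

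Other splits of the libraries were counted for each comparison of 3 libraries with 3. In all 12, 1 of the 10 splits, the real one, gave the largest count by edgeR, between 7304 genes (U937 DKO against SKO) and 12413 (TPA response in DKO). The highest other split called 0 genes in each, with at most 741 genes at an unadjusted p under 0.05 (THP-1 SKO against sgControl, 9180 for the real split). Other splits were not run with DESeq2, and 10 splits are too few for a share under 0.05. For the 4 differences of effects, 1 of the 100 splits drawn, the real one, was as large as the real count. These splits mix away the knockout effects too, so they test whether there is any effect, not a difference between effects, and leave open whether chance gives that difference. The real and highest other counts were 6405 and 6155 for SKO with TPA, 8425 and 7789 for DKO with TPA, 8770 and 5437 for SKO between the lines and 10179 and 6114 for DKO between the lines. The highest others came from the 19 splits that left the labels of 1 condition or line whole, and thus hold its real effect. The exchange of all labels in 1 of them was not drawn. Splits that mixed the labels in both called at most 1 gene, and at most 815 at an unadjusted p under 0.05.

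In U937 DKO, the chromosome 19 median was 0.28 above all genes. It was 0.48 over the 330 genes below 20 Mb, -0.05 from 20 to 40 Mb and 0.1 beyond. Below 20 Mb, SKO had 0.37, and under TPA SKO had 0.41 and DKO 0.45. MOLM-13 SKO had 0.13 there, OCI-AML-3 DKO 0.1, and THP-1 -0.02 (SKO) and -0.09 (DKO). Without numbered ZNF genes, tested as the source, the U937 DKO median was 0.31 over 601 genes. The 105 ZNF genes had 0.12, which argues against that source.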
